A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

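Total RNA of 6 yeast samples, 3 labelled K91A and 3 labelled WT, was hybridised to single-sample oligonucleotide arrays in which each gene is covered by 1 or more probe sets. The deposited table gives 1 intensity per probe set and array on a linear scale. How the authors made these intensities from the scans (software, background correction, scaling) is not given in the sources used here. The medians of the deposited intensities differed between arrays, and K91A 3 was written with more decimals and other empty cells than the other 5. On K91A 3 the ratio of middle to 3' signal of the Lys control was 0.478, against 5.2 to 8.61 on the others.

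Samples were grouped by their titles. K91A 3 has a title that says K91A and a description that says WT. It was kept as K91A because another array is WT replicate 3 in both fields, and results without it and with it as WT were computed. The numbers of the replicates were not used to pair samples.

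Probe sets were named through the platform annotation, with symbols updated by Entrez identifier from a table of RefSeq genes (assembly R64), which was also used for gene order, biotype and coding length. Of 9275 probe sets other than controls, 6504 had 1 gene symbol, all of which were found in the RefSeq table, 328 had several and 2443 had none in the annotation used here. No gene was named from a probe set with several gene symbols, and histone probe sets of this kind are described by the gene pair they share. Some probe sets with 1 symbol, such as those of AAD4 and most tRNA genes, have identifiers that mark probes shared within a family. Their values may include other family members. Among the probe sets tested, 284 had several symbols and 1104 none.

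Values were set to log2(intensity + 16), values below 0 would have been set to 0, and arrays were quantile normalized because their quartiles differed by over 0.1. Fold changes are on this scale, which understates changes of dim probe sets. Left out were the 60 controls, 33 probe sets with fewer than 2 values in a group (22 of them empty on every array) and the 2311 with the lowest mean, 25% of the rest. Differences, K91A minus WT, were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), and p-values were adjusted with the Benjamini-Hochberg method over all probe sets tested at a threshold of 0.05. Where a gene had several probe sets, the one with the highest mean stood for it. The sentences that give an adjusted p for a gene refer to this limma test.

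Before the data were examined, 38 gene lists were fixed: core histones, histone variants and linker, histone chaperones and chromatin assembly, silencing factors, silent mating loci, a-specific, alpha-specific and haploid-specific genes, pheromone response, meiosis and sporulation, DNA damage response, ribosomal proteins, ribosome biogenesis, general stress, heat shock chaperones, oxidative stress, phosphate regulon, glucose-repressed genes, respiratory chain and ATP synthase, citrate cycle, glycolysis, amino acid biosynthesis, sulfur and methionine, strain markers, purine and one-carbon, G1/S, G2/M and M/G1 genes, iron regulon, zinc regulon, cell wall integrity, ergosterol biosynthesis, proteasome, unfolded protein response, subtelomeric families, nitrogen catabolite repression, drug efflux and thiamine. Lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, adjusted over the 36 lists tested. Fry tests whether a list's genes move on balance 1 way and does not compare the list with other genes. Genes near chromosome ends were the 10 outermost protein-coding genes of each arm by gene order, set against 10000 random sets of the same size matched on mean level. Ratios of control probe sets were compared with an exact two-sided permutation test.

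The genes named follow a rule fixed before the data were examined: all core histone genes, the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups do not overlap and whose probe set has 1 symbol, up to 4 members with the smallest p of each list described, and the marker genes HIS3, LEU2, URA3, TRP1, LYS2, MET17 and ADE2. Genes named outside the rule are said to be so.

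The alternatives were the replicate number as a block, K91A 3 left out or counted as WT, each array left out in turn, a pseudocount of 1 or 64, the values as deposited, median centring, no filter or a filter at the median, no mean-variance trend, array weights, Welch's test per probe set, other list tests, 5 or 20 outermost genes, probe sets with no family mark, and probe sets above the median for the correlations. Chosen after seeing the data were protein-coding genes alone, the same with each array's trend on coding length removed, WT 1 and WT 2 averaged, and the estimated correlation for genes near chromosome ends. The procedure was tested on simulated data for 6931 probe sets in 3 against 3 arrays with 50 changed probe sets at each of 4 sizes of log2 change. It recovered 0 of 50 at a log2 change of 0.5, 15 of 50 at 1, 37 of 50 at 2 and 49 of 50 at 4, and 6 of its 114 calls were of unchanged probe sets. A list shifted by 1 was called, and 0 of the 35 other lists were. The simulated probe sets were drawn independently, whereas the correlation estimated within the real lists was -0.28 to 0.82. The simulation therefore does not show how often lists of correlated genes are called wrongly. Its share of changed probe sets was also small, whereas 30.2% of probe sets passed in the real data. The same adjusted threshold was thus stricter in the simulation, and its recovery is not that of the real test. Figures were drawn with matplotlib 3.10.9.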

Results

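Transcript levels were measured in budding yeast (Saccharomyces cerevisiae) on 6 single-sample oligonucleotide arrays. The arrays written here as K91A 1 to K91A 3 came from a strain in which lysine 91 of histone H4 is replaced by alanine (K91A). WT 1 to WT 3 came from a strain with unchanged histone H4 (WT). Lysine 91 lies in the folded core of histone H4, outside the tail that carries most of the well-known modifications. Per the labels, the cells grew in YPD, a rich glucose medium, and total RNA was taken during exponential growth. The table held intensities of 9335 probe sets, of which 60 were controls, and 6931 were tested after the dimmest 25% were left out. Median intensity was 2564, 2040 and 745 on K91A 1, 2 and 3, and 2659, 3116.5 and 1828 on WT 1, 2 and 3. No detection calls came with the values, so whether a probe set lay above background is unknown, and the number of arrays limits the precision. K91A 3 was grouped by its title, whereas its description calls it a WT replicate. Its values also had up to 6 decimals where the other 5 arrays had 1, and 51 empty cells where the others had 33. Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these samples.

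The WT arrays resembled each other more than the K91A arrays did. Pearson's r of log2 values across probe sets was 0.918 to 0.976 between WT arrays, 0.764 to 0.870 between K91A arrays and 0.644 to 0.779 between the groups. WT 1 and WT 2 were the most alike pair. The first principal component held 59.2% of the variance and placed all 3 K91A arrays, K91A 3 included, on 1 side and the WT arrays on the other. The second component held 21.8% and spread the K91A arrays, with K91A 2 and K91A 3 at its ends. With K91A 3 counted as WT, the gap between the mean correlation within and between groups was 0.0623 in place of 0.184, and limma called 0 probe sets, with 1056 at an unadjusted p under 0.05.

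The ratio of signal from the 5' end to signal from the 3' end of the actin transcript, a measure of RNA integrity and labelling, differed between the groups. It was 0.861 ± 0.017 on the K91A arrays and 0.196 ± 0.146 on the WT arrays (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). WT 3 had a ratio of 0.365, and WT 1 and WT 2 had 0.110 and 0.114. The ratio of SRB4 was 0.319 ± 0.147 against 0.126 ± 0.044 (n = 3 each, exact p = 0.1), and that of SPT15 was 0.481 ± 0.187 against 0.223 ± 0.194 (n = 3 each, exact p = 0.2). Signal also moved with coding length across genes, which are not independent replicates. Spearman's rho of level with length was -0.0644 to -0.104 on the K91A arrays and -0.228 to -0.243 on the WT arrays, and that of the log2 fold change with length was 0.216 over 5009 protein-coding genes. Of the 1002 shortest genes (78 to 678 nt) 87 were higher and 230 lower in K91A. Among the longest (2142 to 14733 nt) 23.3% were higher and 9.81% lower, against 8.68% higher among the shortest.

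**Figure D1:**
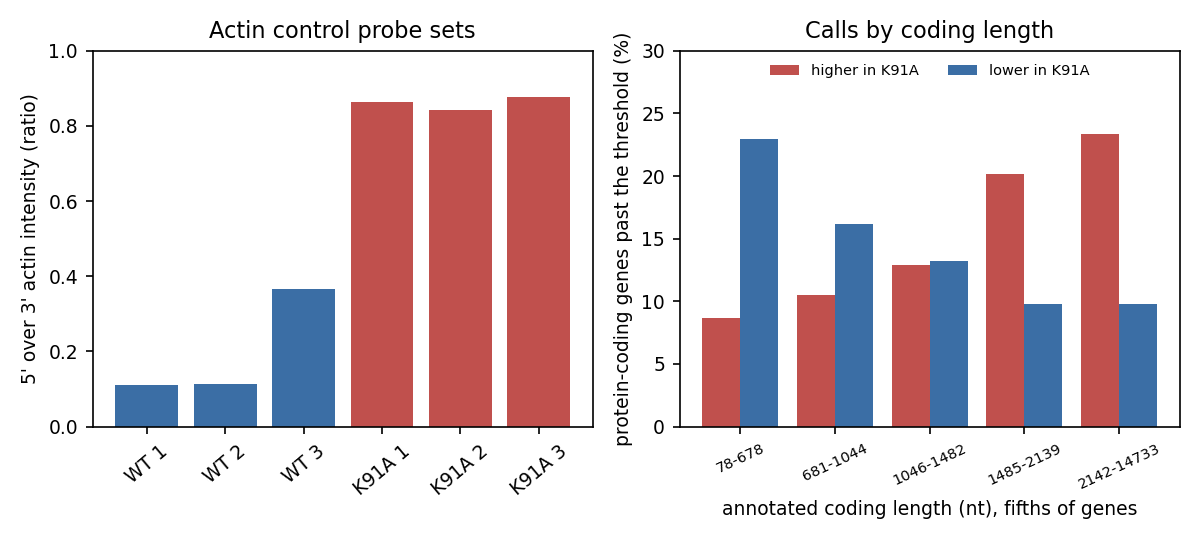
The left panel shows the 5' over 3' intensity ratio of the actin control probe sets as 1 bar per array, WT in blue and K91A in red. The right panel shows, for 5 classes of annotated coding length in nt, the percentage of protein-coding genes that were higher (red) or lower (blue) in K91A, with higher calls at 8.68% in the shortest class and 23.3% in the longest.

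The first comparison asked whether the transcript of the mutated histone itself differed, and no difference past the threshold was found. The probe set shared by HHF1 and HHF2, the 2 genes for histone H4, had a log2 fold change of -0.36 (SE 0.17, limma adjusted p = 0.142, n = 3 each), K91A minus WT. HTB2, a gene for histone H2B, was lower in K91A, with a log2 fold change of -1.45 (SE 0.39, adjusted p = 0.0314). HTB1, the other H2B gene, had a log2 fold change of 0.06 (SE 0.14, adjusted p = 0.771). The tested probe sets shared by HHT1 and HHT2 had values of 0.05 and 0.31, those shared by HTA1 and HTA2 had 0.06 and 0.28, and none passed. A point mutation need not alter the transcript level, so these values do not check the labels. Without K91A 1 the H4 probe set passed at -0.53 (adjusted p = 0.0453). The HTB2 call ended without K91A 1 (adjusted p = 0.0567), WT 1 (0.0702), WT 2 (0.0995) or WT 3 (0.0925), and with the length trend removed (0.0515).

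The second comparison asked which genes differed between the K91A and WT strains. The most extreme values belonged to TRP1 and ADE2, biosynthetic genes that are also common selectable markers of laboratory strains. TRP1, an enzyme of tryptophan synthesis, was 38.8-fold higher in K91A (log2 fold change 5.28, 95% interval 4.60 to 5.96, limma adjusted p = 0.0012). Its log2 level was 13.62 ± 0.54 against 8.34 ± 0.10 (SD, n = 3 each). ADE2, an enzyme of adenine synthesis, was 53.0-fold lower (log2 fold change -5.73, 95% interval -6.24 to -5.22, adjusted p = 0.000186). Its log2 level was 9.07 ± 0.32 against 14.80 ± 0.09 (n = 3 each). ADE2 lay at the 15.8 to 23.1 percentile of its array on the K91A arrays and at the 98.7 to 99.1 percentile on the WT arrays. TRP1 lay at the 9.93 to 11.5 percentile on the WT arrays. On their dim side both thus lay among the dimmest 25% of probe sets, where signal may be background, so the measured folds may understate the differences. Of the other marker genes, LEU2 was higher with a log2 fold change of 0.82 (adjusted p = 0.0233) by its brightest probe set, and 1.89 (adjusted p = 0.014) and 1.99 (adjusted p = 0.0535, not past) by the others. MET17 (0.73, adjusted p = 0.172) and URA3 (0.54, adjusted p = 0.264) did not pass, while HIS3 and LYS2 were left out as dim. The call of the brightest LEU2 probe set ended with median centring (0.65, adjusted p = 0.101) and on the values as deposited, and without K91A 1 (adjusted p = 0.0509), K91A 3 (0.0541), WT 1 (0.0868) or WT 2 (0.102). Without K91A 2, MET17 (1.17, adjusted p = 0.0149) and URA3 (0.92, adjusted p = 0.0313) passed.

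**Figure D2:**
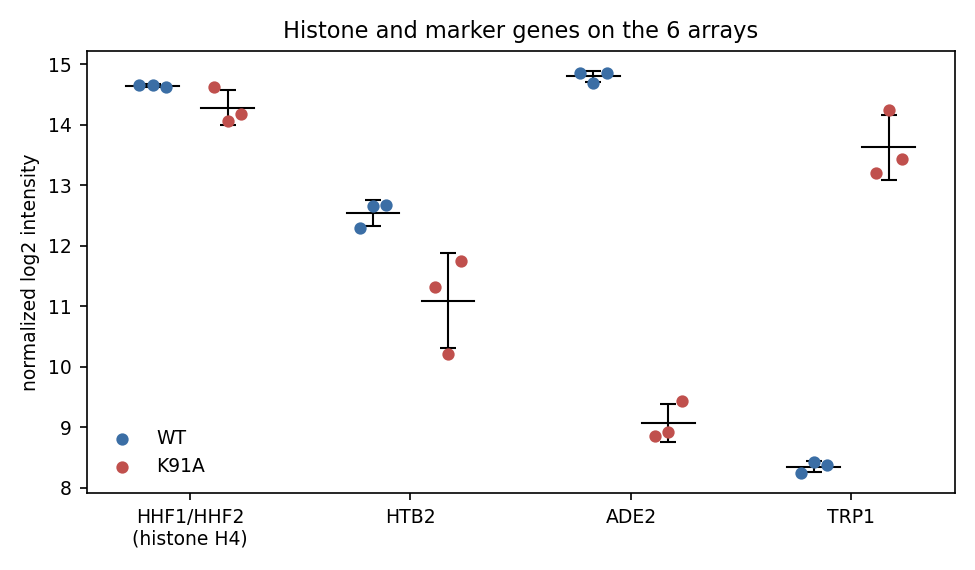
Normalized log2 intensity of the shared histone H4 probe set, HTB2, ADE2 and TRP1, with 1 point per array (WT in blue, K91A in red), a line at the mean of 3 arrays and bars of 1 SD. ADE2 was near 14.80 on the WT arrays and 9.07 on the K91A arrays, and TRP1 was near 8.34 and 13.62.

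TRP1 was followed among the 12 largest increases by genes of varied functions. OSI1, known to be induced by oxidative stress, had a log2 fold change of 4.20 (SE 0.43). The old yellow enzyme OYE3 had 3.40 (SE 0.44) and the glutathione transferase GTT2 had 3.30 (SE 0.24). The cell wall protein PIR3 rose by 2.78 (SE 0.22), the cell cortex protein FMP45 by 3.07 (SE 0.33) and YNL190W by 3.46 (SE 0.58). The others were NCA3 (3.15), the dynein subunit PAC11 (2.93), the septin-associated kinase KCC4 (2.91), the coat protein SEC16 (2.81) and the cyclin-like CLG1 (2.68). Other probe sets of KCC4 (-0.51) and SEC16 (0.82 and -0.25) did not pass, so these 2 increases rest on part of their probe sets, while another of SEC16 (1.75) passed. HAC1, the regulator of the unfolded protein response, had 2 probe sets at 3.04 and 3.02 that passed and 2 at 1.20 and 0.84 that did not. The one with the highest mean, at 0.84 (adjusted p = 0.179), stood for the gene, so HAC1 is not among the 12, and it was named after its values were seen. Without WT 3 that probe set passed (1.34, adjusted p = 0.0126), and on the values as deposited it was at -0.05. All 12 passed limma's test, and the CLG1 call ended without WT 1 (2.29, adjusted p = 0.0633) or WT 2 (2.42, adjusted p = 0.0663). After ADE2, the largest decreases were non-coding: the small nucleolar RNA SNR189 (-4.15, SE 0.78), 9 tRNA genes between -3.98 and -3.51, among them YNCJ0008W (-3.98) and CDC65 (-3.51), and the ribosomal RNA gene RDN18-1 (-3.58). SNR189 was at 10.19, 9.48 and 6.99 on K91A 1, 2 and 3, so K91A 3 enlarged its fall. The probe sets of YNCJ0008W, CDC65 and RDN18-1 have identifiers that mark shared probes, so their values may not belong to 1 gene. Protein-coding decreases were ranked after the data were seen. They were led by YBL028C (-2.87), YDR034C-A (-2.86) and CGR1 (-2.68), a factor of ribosomal RNA processing, and included COS10 (-2.40), the histidine enzyme HIS1 (-2.20), the purine enzyme ADE4 (-2.19) and the prefoldin subunit GIM4 (-2.18). The other probe set of YDR034C-A was at 0.66 and did not pass. YBL028C and COS10 fell below the filter on dim probe sets without any 1 WT array, and CGR1 without WT 3, so those settings gave them no value.

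In all, 2091 of 6931 probe sets (30.2%) passed limma's test at an adjusted p of 0.05. Of these, 1068 were higher and 1023 lower in K91A, and 1392 differed by over 2-fold. With 1 probe set per gene, 757 of 5009 protein-coding genes were higher and 721 lower. The groups did not overlap for 51.1% of probe sets, where chance gives 10%. Of 190 genes with several tested probe sets (those whose identifiers mark mixed probes not counted), 112 had at least 1 call, 84 of them were called by only some of their probe sets, and 5 were called in opposite directions. The count was 925 without WT 1, 841 without WT 2 and 1867 without K91A 3, and 887 with WT 1 and WT 2 averaged into 1 sample, a setting chosen after seeing the data. On the values as deposited the median of all probe sets was -0.82 in place of -0.07, and 32 were higher and 671 lower, so directions here are relative to the bulk of transcripts. The values as deposited keep differences in level between arrays. K91A 3 had the lowest median intensity (745, against 1828 to 3116.5 on the other 5). Whether the signs as deposited rest on that array was not tested.

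Non-coding RNAs were lower in K91A as a class. Of 84 tRNA probe sets 83 fell, with a median log2 fold change of -2.16, and 82 of the 84 had identifiers that mark probes shared within a family. Of 45 small nucleolar RNA probe sets 28 fell, with a median of -1.06. Falls were also called for 3 of 4 spliceosomal snRNA, 3 of 5 ribosomal RNA, both of 2 telomerase RNA and the 1 RNase P RNA probe sets, and for 2 of 7 probe sets of the ribosomal RNA precursor, which are not among those 5. None in these classes rose. Protein-coding probe sets had a median of -0.07. The 5' over 3' actin ratio differed between the same arrays (0.861 against 0.196), and the labels give total RNA for all 6.

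Groups of genes fixed before the data were examined were then compared between the strains. Genes repressed by glucose rose the most as a group. Of 32 measured, 20 rose and 0 fell (21 rose when adjusted over the list alone), with a median log2 fold change of 1.56. The peroxisomal thiolase POT1 had 2.31, the gluconeogenic enzyme PCK1 1.73 and the glycerol enzyme GUT2 2.24 (camera adjusted p = 6.24e-09, adjusted p = 0.563 with an estimated correlation). Genes of sulfur and methionine metabolism also rose, 13 of 25 with 0 lower (13 adjusted over the list alone, median 0.99, camera adjusted p = 7.64e-05, adjusted p = 0.197 with an estimated correlation), with MET2 at 1.99, the sulfate transporter SUL2 at 1.63 and MET1 at 1.47. Of 25 iron regulon genes 12 rose and 2 fell (13 and 2 adjusted over the list alone, median 0.75, camera adjusted p = 0.000263, adjusted p = 0.197 with an estimated correlation). They included the siderophore transporter ARN1 (2.18) and the reductases FRE2 (1.80) and FRE1 (1.29), while FET4 (-1.19) and ATX1 (-0.75), named after their values were seen, fell. The FET4 call ended without WT 1 (adjusted p = 0.0507) and the ATX1 call without WT 1 (0.0885), WT 2 (0.0939) or K91A 3 (0.0502). Without WT 1 and without WT 2 the counts higher were 8 and 6 for sulfur genes and 6 and 5 for iron genes, and camera still called both lists. On the values as deposited camera called all 3 lists, but 0 members rose in any, 2 iron genes fell, and the medians were 0.78 for glucose-repressed, 0.33 for sulfur and 0.18 for iron genes. The actin 5' over 3' ratio was also higher on the K91A arrays (0.861 against 0.196).

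Camera called the general stress, oxidative stress and cell wall lists higher relative to other genes. On the values as deposited, however, their medians were below 0, where that of all probe sets was -0.82. Of 42 general stress genes 14 rose and 0 fell (17 adjusted over the list alone, median 0.66, -0.25 as deposited), with GND2 at 2.20, XBP1 at 1.93 and GDB1 at 1.75 (camera adjusted p = 1.97e-07, adjusted p = 0.581 with an estimated correlation). Of 17 oxidative stress genes 8 rose and 0 fell (8 adjusted over the list alone, median 0.72, -0.18 as deposited). GTT2, OYE3, the transporter FLR1 (2.38) and the sulfiredoxin SRX1 (2.02) led this list (camera adjusted p = 0.000263, adjusted p = 0.563 with an estimated correlation). Of 26 cell wall genes 10 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.54, -0.31 as deposited, camera adjusted p = 0.000272, adjusted p = 0.563 with an estimated correlation), led by PIR3, and the member that fell was GAS1 (-0.68), named after its value was seen. The GAS1 call ended without K91A 1 (adjusted p = 0.0625), WT 1 (0.125), WT 2 (0.133) or WT 3 (0.109). Of 18 heat shock chaperones 0 passed limma's test over all probe sets or adjusted over the list alone, with 1 at an unadjusted p under 0.05 (median -0.22, camera adjusted p = 0.618, fry adjusted p = 0.617), while 1 rose without K91A 2 and 2 fell without WT 3. Without K91A 1, WT 1 and WT 2 in turn, 8, 9 and 8 general stress genes and 5, 3 and 1 cell wall genes rose, and camera still called both lists. On the values as deposited 0 general stress, 2 oxidative stress and 2 cell wall genes rose.

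Camera called the lists of ribosome production and of purine and amino acid synthesis lower relative to other genes, and the share of members that fell varied. Of 58 ribosome biogenesis genes 28 fell and 1, RRN3 (0.82, named after its value was seen), rose (37 and 1 adjusted over the list alone, median -0.82, camera adjusted p = 2.31e-07, adjusted p = 0.563 with an estimated correlation). NOP12 had -1.82, IMP4 -1.57, ENP2 -1.55 and RLP7 -1.43. Of 80 ribosomal protein genes 10 fell and 0 rose, but 1 fell when adjusted over the list alone. The share that fell was below that of all probe sets (1023 of 6931). It was above it in some settings, among them the values as deposited (29 of 80, 67 adjusted over the list alone, against 671 of 6931). The same held without K91A 1 (10 of 80 against 747 of 6909) and without K91A 2 (17 of 80 against 1161 of 6909). The median of the ribosomal protein genes was -0.43 and 77 of the 80 values were negative (camera adjusted p = 0.000263, adjusted p = 0.717 with an estimated correlation), with RPL22B at -1.79. Of 15 purine and one-carbon genes 9 fell (9 adjusted over the list alone, median -1.11, camera adjusted p = 0.00268, adjusted p = 0.273 with an estimated correlation), with ADE17 at -1.75 and ADE1 at -1.64 beside ADE2 and ADE4. Their 1 increase was ADE16 (0.73, named after its value was seen, -0.12 as deposited). Of 47 amino acid synthesis genes 13 fell and 5 rose (19 and 5 adjusted over the list alone, median -0.52, camera adjusted p = 0.0148, adjusted p = 0.588 with an estimated correlation). HIS1 (-2.20), GCV3 (-1.60) and GCV1 (-1.43) fell, and CPA1 (1.31), SNO1 (2.09), CIT2 (0.99), SNZ1 (0.95) and SER3 (0.81, -0.0098 as deposited) rose, the last 4 named after their values were seen. Without WT 1 and without WT 2 the counts lower were 12 and 9 for ribosome biogenesis, 1 and 1 for ribosomal proteins, and 5 and 5 for amino acid genes, and without WT 3 they were 4 for ribosomal proteins and 8 for amino acid genes. The count for amino acid genes that rose was 2 without WT 1 or WT 2 and 3 without WT 3. On the values as deposited 16 ribosome biogenesis, 9 purine and 13 amino acid genes fell, 0 members of these lists rose, and camera called all 4 lists. Calls for 4 of the increases ended without 1 array: RRN3 without K91A 1 (adjusted p = 0.0665), WT 1 (0.0717), WT 2 (0.0863) or WT 3 (0.0628), ADE16 without K91A 1 (0.0627), WT 1 (0.093), WT 2 (0.11) or K91A 3 (0.0654), CIT2 without WT 1 (0.063), WT 2 (0.0783) or WT 3 (0.0745), and SNZ1 without WT 1 (0.0714) or WT 2 (0.0808). The SER3 call ended without K91A 1 (adjusted p = 0.0804), K91A 2 (0.0616), WT 1 (0.112), WT 2 (0.0676) or WT 3 (0.0921).

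**Figure D3:**
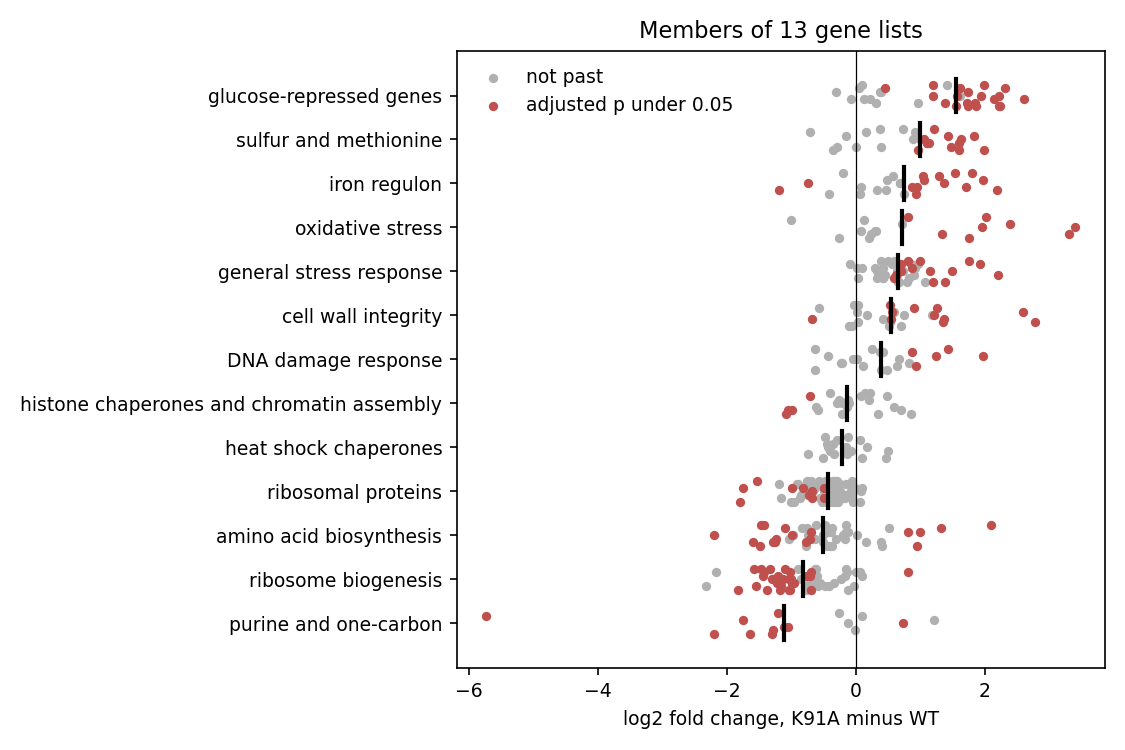
Log2 fold change (K91A minus WT) of each measured member of 13 gene lists, in red where limma's adjusted p was under 0.05 and in grey otherwise, with a black bar at the list's median. Medians run from 1.56 for glucose-repressed genes to -1.11 for purine and one-carbon genes.

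Over the 36 lists tested, camera with a preset correlation called 14 higher and 4 lower. With an estimated correlation camera called 0, with 3 lists at an unadjusted p under 0.05, and fry called 15. Fry did not call 7 of the 18, namely general stress (adjusted p = 0.0973), DNA damage (0.0943), respiratory chain (0.197), pheromone response (0.0658), nitrogen catabolite repression (0.118), ribosomal proteins (0.199) and amino acid synthesis (0.0606). It called 4 others: phosphate (0.00357), zinc (0.0138), unfolded protein response (0.0135) and drug efflux (0.0115). The other splits of the same 6 arrays gave 9 to 17 lists each, against 18 for the real one. Camera at the preset correlation thus called many lists for groupings that mix the strains.

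Lysine 91 of histone H4 has been studied in chromatin assembly, silencing and DNA repair, and lists for these were compared next. Of 21 DNA damage response genes 5 rose and 0 fell (4 adjusted over the list alone, median 0.39, -0.38 as deposited). These were HUG1 (1.97) and RNR3 (1.24), both known targets of the damage checkpoint, the checkpoint kinase MEC1 (1.43), the repressor RFX1 (0.93) and the recombination gene RAD54 (0.87), the last named after its value was seen. Camera called the list (adjusted p = 0.022, adjusted p = 0.588 with an estimated correlation), but not without K91A 1 (adjusted p = 0.0572), on the values as deposited (0.0582), with probe sets below the median left out (0.0603), with K91A 3 counted as WT (0.124) or with the length trend removed (0.0864). The count of members higher was 3 without K91A 1, K91A 3, WT 1 or WT 3, 2 without WT 2 and 10 without K91A 2, and 1 member fell without K91A 3, while 0 rose as deposited. The RNR3 call ended without WT 2 (adjusted p = 0.0547). The RFX1 call ended without K91A 1 (0.0773), K91A 3 (0.0535), WT 1 (0.0679), WT 2 (0.0626) or WT 3 (0.0503), and the RAD54 call without K91A 1 (0.123), K91A 3 (0.102), WT 1 (0.074), WT 2 (0.129) or WT 3 (0.125). Of 23 histone chaperone and chromatin assembly genes 4 fell and 0 rose (3 adjusted over the list alone, median -0.13, camera adjusted p = 0.618): VPS75 (-1.06), SPT6 (-1.09), KAP123 (-0.99) and SPT4 (-0.71). VPS75 alone kept its call without WT 1 (adjusted p of the others 0.0676 to 0.127) or WT 2 (0.0758 to 0.127). The SPT6 call also ended without K91A 1 (adjusted p = 0.0676) or WT 3 (0.0579), the SPT4 call without K91A 1 (0.0976) or K91A 3 (0.0686), and without K91A 2 4 members of the list rose. These counts use 1 probe set per gene, by which 840 of all 5152 genes tested fell. The chromatin assembly gene CAC2, named after its values were seen, had 3 probe sets at 0.69 to 1.99, and 2 of them were called higher. Among 15 silencing factors HST2 rose (1.89) and ABF1 fell (-0.84), also adjusted over the list alone (camera adjusted p = 0.71), and the ABF1 call ended without WT 1 (adjusted p = 0.0908) or WT 2 (0.0897). Without K91A 1 2 silencing factors fell, and without K91A 2 2 rose. Of 3 genes for histone variants and linker histone, HTZ1 fell (-0.69, adjusted p = 0.0476, also adjusted over the list alone), a call that ended without any 1 of the 6 arrays (adjusted p 0.0517 to 0.16), and camera did not call the list (adjusted p = 0.31). On the values as deposited 1 histone chaperone gene fell, and 0 silencing factors and histone variants passed.

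Genes that differ between yeast mating types were compared as a check on cell type. The a-factor genes MFA1 (1.40) and MFA2 (0.99) rose among 3 a-specific genes (3 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.517 with an estimated correlation), and STE6 had 0.78 (adjusted p = 0.0887). The MFA2 call ended without WT 2 (adjusted p = 0.0549), the list was not called with K91A 3 counted as WT (0.0723), and without K91A 1 too few members were measured to test it. STE6 passed with median centring (0.90, adjusted p = 0.0333). Among 5 alpha-specific genes MF(ALPHA)2 rose (1.19), a call that ended without WT 1 (adjusted p = 0.0667) or WT 2 (0.07), while STE3 had -0.58 and SAG1 -0.30 without passing (1 adjusted over the list alone, camera adjusted p = 0.7). Of 15 haploid-specific genes 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.972). The G protein subunit GPA1 fell (-2.09), and AXL1 (0.83) and AGA1 (0.76, -0.09 as deposited) rose. Both calls ended without WT 1 (adjusted p = 0.0882 and 0.102), WT 2 (0.0638 and 0.113) or WT 3 (0.06 and 0.0734), and the AGA1 call also without K91A 1 (0.0878) or K91A 3 (0.0867). Without K91A 3 3 members of the list fell. On the values as deposited 0 a-specific and 0 alpha-specific genes passed, and 0 haploid-specific genes rose and 2 fell. The lists of silent mating loci and core histones had fewer than 3 measured genes of their own probe sets and were not tested.

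Genes near chromosome ends, where silencing acts, were higher in K91A relative to other genes. Of 158 measured genes among the 10 outermost of each chromosome arm, 64 were higher and 10 lower (68 and 14 adjusted over the list alone). Their median log2 fold change was 0.64 against -0.12 for all other genes (camera p = 1.72e-07, p = 0.0417 with an estimated correlation, the second test chosen after seeing the data), and on the values as deposited it was -0.05 against the median of -0.82 for all probe sets. It lay above all of 10000 random sets matched on mean level, 95% of which had medians between -0.25 and 0.04. These sets were drawn from genes read on the same arrays. Their range thus holds no spread between arrays and no correlation among genes of the set, which was estimated at 0.045. Splits of the arrays that mix the strains gave medians of up to 0.29 in size. The genes with the smallest p in the set were GTT2, YCR102C (2.09), FRE2 (1.80) and YKL222C (1.94), named after their values were seen. GTT2 and FRE2 also belong to the oxidative stress and iron lists, and PCK1 (1.73), next by p, to the glucose-repressed list. Whether the shift holds without such genes was not tested. The shift was larger for the 5 outermost genes per arm (0.93) and smaller for 20 (0.15, p = 0.168 with an estimated correlation). Of 27 genes in the list of subtelomeric families, 12 rose and 1 fell (16 and 2 adjusted over the list alone, camera adjusted p = 0.00014, adjusted p = 0.563 with an estimated correlation). This list overlaps the set of the 10 outermost genes per arm, as FLO10, AAD4 and COS10 are in both, so the 2 results are not independent. FLO10 (2.58), AAD4 (2.44) and DAN4 (1.76) rose and COS10 (-2.40) fell, and without WT 2 7 rose and as deposited 1, while COS10 had no value without any 1 WT array. Of 18 probe sets shared by the YRF1 helicase genes of the Y' elements, 4 were higher and 0 lower, with values between -1.06 and 3.78.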

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

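The settings with protein-coding genes alone, with or without the length trend, with WT 1 and WT 2 averaged, and with an estimated correlation for genes near chromosome ends were chosen after seeing the data. The other settings were fixed before the data were examined, and the cause of a changed value was not tested unless fewer arrays or probe sets entered by construction.

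The count of 2091 probe sets (1068 higher, 1023 lower) was 0 with K91A 3 counted as WT (0 and 0), 703 as deposited (32 and 671, or 4.55% higher in place of 51.1%), 1372 with probe sets below the median left out (686 and 686), 887 with WT 1 and 2 averaged (506 and 381) and 339 with Welch's test after adjustment (157 and 182). Array weights gave 1576 lower. Leaving out 1 array gave 841 to 2300 probe sets, 479 to 1139 higher and 362 to 1161 lower, fewest without WT 2. Of the 2091, 73 changed sign as deposited and 0 with median centring (median of all probe sets -0.18). The H4 probe set ranged from -0.53 (adjusted p = 0.0453, without K91A 1) to -0.25 over arrays left out, and was -1.29 as deposited (adjusted p = 0.068) and -0.64 with median centring (0.0886). The replicate block gave 1535 probe sets, 1486 of them among the 2091. It gave 17 lists, as the respiratory chain was not called (camera adjusted p = 0.057). With it 24 of the genes named or leading a list were no longer called, LEU2 (limma adjusted p = 0.0508) among them. Samples with the same number deviated with r of 0.167, -0.152 and -0.00523, so the numbers do not pair them, and not every sample correlated best with its own number.

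The number of lists, 18, was 0 with an estimated correlation and 13 to 19 in the other settings run. The shift near chromosome ends stayed past camera's threshold and up relative to other genes in each setting run, except 20 genes per arm with an estimated correlation (p = 0.168), and its median was -0.05 as deposited. The gap between correlations within and between groups, 0.184, was 0.0623 with K91A 3 counted as WT, 0.0868 with no filter, 0.266 with probe sets below the median left out, 0.291 over those above it and 0.149 to 0.228 over arrays left out.

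As deposited, AGA1 (-0.091), LSC1 (-0.30), SED1 (-0.41), ADE16 (-0.12), SER3 (-0.0098), TEC1 (-0.12) and PST1 (-0.30) reversed without passing, and 89 of the genes named or leading a list lost their call. Those values keep the level of each array, which was lowest on K91A 3. Without WT 1 and without WT 2, 65 and 68 lost it. With no detection calls, what signal over background limits is unknown.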

Other observations

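The gene lists, the other splits of the arrays and the settings with other arrays, scaling, filter or weights were fixed before the results were seen. The settings with protein-coding genes alone, with or without the length trend, and the tests of explanations other than those splits were chosen after.

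Genes of several nutrient pathways not described above also differed. For comparison, 759 of all 5152 genes tested rose, by 1 probe set each. The share that rose was near this in the nitrogen and respiratory chain lists. Of 9 thiamine genes 5 rose (6 adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.581 with an estimated correlation): the transporter THI7 (2.14), THI21 (1.37), THI22 (1.19), THI4 (1.07) and THI6 (0.74), the last named after its value was seen. Camera did not call the list with K91A 3 counted as WT (adjusted p = 0.104), where 0 rose, and as deposited 0 rose and 1 fell. Without K91A 1 or any 1 WT array 3 rose, and the calls of THI4 and THI6 ended without K91A 1 (adjusted p = 0.0789 and 0.0823), K91A 3 (0.0627 and 0.0754), WT 1 (0.0541 and 0.102), WT 2 (0.0979 and 0.0922) or WT 3 (0.0809 and 0.0863). The proline permease PUT4 (2.59), GDH2 (1.55), PUT1 (1.08) and UGA4 (1.04, with another of its probe sets at -0.10) rose among 24 genes under nitrogen catabolite repression (3 adjusted over the list alone, camera adjusted p = 0.0303, adjusted p = 0.601 with an estimated correlation), a list not called without K91A 3 (adjusted p = 0.0621), K91A 2 (0.0582) or WT 3 (0.111), with K91A 3 counted as WT (0.146), with no filter (0.066), with probe sets below the median left out (0.0807), with array weights (0.133) or with the length trend removed (0.0864). Without K91A 1 or WT 2 2 rose. The PUT1 call ended without K91A 1 (adjusted p = 0.065) or WT 2 (0.0649), and the UGA4 call without K91A 1 (0.0999), K91A 3 (0.0765), WT 1 (0.0711), WT 2 (0.103) or WT 3 (0.1). In the respiratory chain 7 of 36 genes rose and 0 fell (5 adjusted over the list alone), led by RIP1 (1.89), CYT1 (1.44) and SDH2 (1.25). Their median was 0.03 (-0.86 as deposited), and camera's call (adjusted p = 0.042, adjusted p = 0.708 with an estimated correlation) ended with median centring (0.576), as deposited (0.909), with array weights (0.298) and without K91A 2 (0.16) or WT 3 (0.3), while without K91A 1, WT 1 or WT 2 4 rose. Of 19 pheromone response genes 6 rose, led by PRM1 (1.20), and of 19 meiosis genes 7 rose, led by CDA1 (1.36) and SGA1 (1.80), with 7 each adjusted over the list alone (camera adjusted p = 0.0333 and 0.0164, adjusted p = 0.581 and 0.563 with an estimated correlation). Without WT 2, 1 pheromone gene and 2 meiosis genes rose. Without WT 1 these counts were 1 and 4, without K91A 3 they were 3 and 4, 3 pheromone genes rose without K91A 1 and 4 meiosis genes without WT 3. The PRM1 call ended without WT 1 (adjusted p = 0.0577) or WT 2 (0.0616), and with the length trend removed neither list was called (0.0916 and 0.0539). Camera also did not call the pheromone list with K91A 3 counted as WT (0.185) or with probe sets below the median left out (0.0807), or the meiosis list with protein-coding genes alone (0.064). As deposited 0 genes of the nitrogen, respiratory chain, pheromone and meiosis lists rose.

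The remaining lists were not called by camera, and in most of them few members kept their call with 1 array fewer. The chaperone LHS1 (-2.07), MPD1 (-1.32), EUG1 (-1.03), SCJ1 (-0.88) and ERV29 (-0.77) fell and ULI1 (0.91) and INO1 (1.15) rose among 17 unfolded protein response genes (2 higher and 7 lower adjusted over the list alone, adjusted p = 0.141). The regulator PHO81 (-0.96), the polyphosphate genes VTC1 (-0.74), VTC2 (-0.76) and VTC3 (-0.92) and GPP2 (-0.89) fell among 16 phosphate genes and GIT1 (0.91) rose (2 higher and 6 lower adjusted over the list alone, adjusted p = 0.14). Drug efflux genes had 6 higher, with GRE2 at 1.67 and PDR10 at 1.64, and 1 lower, QDR2 (-1.28), of 16 (6 and 2 adjusted over the list alone, adjusted p = 0.079), and the list was called without WT 1 (0.028) or WT 2 (0.0417). ZPS1 (1.33), ZRT1 (1.99), ZRT2 (1.20) and INO1 rose and FET4 (-1.19) and IZH2 (-0.87) fell among 12 zinc genes (4 and 2 adjusted over the list alone, adjusted p = 0.31). The cyclin CLN3 (1.99), TEC1 (0.74, -0.12 as deposited) and PST1 (0.57, -0.30 as deposited) rose and DSE1 (-1.54), DSE3 and SCW11 (-1.05) fell among 19 daughter cell genes (3 and 3 adjusted over the list alone, adjusted p = 0.617). HCM1 (1.49) rose and MNN1 (-1.66) and CTF18 (-1.21) fell among 30 G1/S genes (0 and 1 adjusted over the list alone, adjusted p = 0.432), and ALK1 (-0.84) and BUD4 (-2.44) fell among 14 G2/M genes (0 adjusted over the list alone, 0.699). MDH1 (1.08), CIT2 (0.99) and LSC1 (0.61, -0.30 as deposited) rose among 11 citrate cycle genes (4 higher and 1 lower adjusted over the list alone, 0.257), and PDC5 (1.31) and PGI1 (1.04) among 16 glycolysis genes (0 adjusted over the list alone, 0.274). CYB5 (-1.53) and ERG4 (-0.87) fell among 25 ergosterol genes (2 adjusted over the list alone, 0.452), and RPN4 (1.22), the regulator of the proteasome genes, rose among 34 genes of that list (0 adjusted over the list alone, 0.71). SCJ1, ERV29, INO1, VTC1, GPP2, QDR2, IZH2, TEC1 and PST1 were named after their values were seen. Of the genes just named, LHS1, MPD1, PHO81, GRE2, PDR10, ZPS1, CLN3, MNN1, MDH1 and CYB5 kept their call with any 1 array left out. Calls of the others ended without WT 1 (adjusted p 0.0507 to 0.134), except those of RPN4 and ZRT2, and without WT 2 (0.0525 to 0.167), except those of DSE1, FET4 and QDR2. Without WT 3 the calls of BUD4, CIT2, CTF18, DSE1, ERV29, EUG1, GIT1, GPP2, INO1, IZH2, PST1, SCJ1, SCW11, TEC1, ULI1 and VTC1 ended (0.0505 to 0.115). Without K91A 1 those of BUD4, DSE1, ERV29, HCM1, INO1, IZH2, LSC1, PDC5, PGI1, PST1, SCW11, TEC1, ULI1 and VTC1 ended (0.0523 to 0.123). Without K91A 3 those of BUD4, CTF18, ERV29, GPP2, PGI1 and PST1 ended (0.0693 to 0.133), and without K91A 2 those of CTF18 and GPP2 (0.0849 and 0.0888). As deposited 0 genes of these lists rose. The counts that fell there were 5 for phosphate, 3 for unfolded protein response, 2 for ergosterol, 1 each for drug efflux, zinc, G1/S, G2/M and proteasome, and 0 for daughter cell, citrate cycle and glycolysis genes. Apart from these, the 6 measured strain markers had a positive median and camera direction but a negative direction with fry, and neither passed.

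Limma called 2091 probe sets for the strains and at most 0 in any other split of the 6 arrays (at most 300 against 3035 at an unadjusted p under 0.05), camera 18 lists against at most 17, and the median near chromosome ends was 0.64 against at most 0.29 in size. The real split ranked first in each (1 of 10 splits), and 10 splits are too few for a share under 0.05. Each other split also mixes the strains, so any difference between the K91A and WT arrays widens the spread within its groups. The absence of limma calls there therefore does not tell the H4 allele from another difference between the same arrays. The different processing of K91A 3 does not account for the whole count, since 1867 probe sets were called without that array, 1645 of them among the 2091. Nor does a trend on coding length, since 1535 protein-coding probe sets were called with that trend removed against 1647 before. What stays open is signal loss that depends on where a probe set lies in its transcript, as positions were not used here, and a strain or culture difference apart from the allele.

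ADE2 and TRP1 separate the strains more widely than any histone gene. If K91A 3 held RNA of the WT strain, as its description says, ADE2 there would lie near the WT level, but it was -5.36 from the WT mean on the log2 scale, where 3 SDs of the WT arrays are 0.27. One candidate explanation for the lower purine genes is the loss of the ADE2 transcript rather than the allele, as the transcription factor Bas1 controls purine, histidine and one-carbon genes together. The 8 genes of this type outside the adenine pathway that were examined (HIS1, HIS4, HIS7, GCV1, GCV2, GCV3, SHM2 and MTD1) fell, with a median of -1.45. They were picked after the falls were seen and belong to the amino acid and purine lists described above, so their falls restate that pattern and do not test the explanation. Without WT 1 the calls of HIS4, HIS7, GCV2, SHM2 and MTD1 ended (adjusted p 0.0536 to 0.096), without WT 2 those of HIS4, GCV2, SHM2 and MTD1 (0.0545 to 0.0742), without WT 3 those of HIS4 (0.0573) and SHM2 (0.0529), and that of HIS4 also without K91A 1 (0.0724) or K91A 3 (0.0554). ADE2 level and H4 allele divide the 6 arrays the same way, so the explanations cannot be told apart here, and strains alike at ADE2 and TRP1 would be needed.

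The fall of non-coding RNAs covers transcripts of all 3 nuclear RNA polymerases. Lower output of RNA polymerases I and III alone would leave most small nucleolar RNAs, made by polymerase II, near the protein-coding median. Their median lay -0.99 from it (bootstrap interval over probe sets -1.48 to -0.87). The interval treats probe sets read on the same arrays as replicates, so it holds no spread between arrays. Length was not matched, and the shortest protein-coding genes (78 to 678 nt) had a median log2 fold change of -0.30. The tRNA probe sets fell further, with a median of -2.16. These values thus speak only to small nucleolar RNAs on these arrays. A lower output of polymerases I and III as part of the fall stays open. Unequal recovery or labelling of RNA without a poly(A) tail stays open. That 96.6% of 145 non-coding probe sets, and 9 of 10 ribosomal RNA controls, had negative values restates the pattern and does not test it. An effect of the H4 allele on these RNAs stays open too and was not tested, as the design holds no second RNA preparation of the same strains.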
